A study of Mus musculus with 46 samples.

How the data were processed

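RNA from liver and white adipose tissue (WAT) of C57BL/6 mice on a high-fat diet (HFD) was sequenced as polyA RNA, per the labels. The labels do not name the fat depot, the library kit or the read layout. There were 46 libraries in 8 groups of organ, sex and treatment, with 6 libraries in each group except male vehicle, which had 5 in each organ.

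The deposited files hold counts, that is whole reads per gene, 1 file per library. Per the submitters' processing notes, STAR 2.4.0i, HTSeq and the genome build mm10 were used; the annotation release and the filters are not given in the sources used here. Each file has 3 columns of counts in the layout of STAR's gene count output, namely 1 without regard to strand and 1 for each strand. Column 4 was used because it held between 96.0% and 96.5% of the sum of both stranded columns in every library, above the minimum of 80%. The unstranded column 2 was an alternative. The 4 totals that name no gene (unmapped, multimapping, no feature and ambiguous reads) stayed out of library sizes and tests. They were 21.0% to 28.9% of a liver library (median 24.3%) and 18.4% to 28.7% of a WAT library (median 23.4%). Reads that map to several places are among these totals, so genes with near-identical copies, such as Saa1 and Saa2, are measured from fewer reads and less surely. Of 55487 gene identifiers, 55227 matched GENCODE M21, whose GRCm38 coordinates are given for named genes. GRCm38 and mm10 are names of the same build. Counts on genes summed to between 20266425 and 57518893 per liver library (median 36541828) and between 20991069 and 32219751 per WAT library (median 25260159).

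Groups were taken from the organ, sex and treatment in the labels, and libraries are named by the number in their titles. The labels number the libraries but do not state that each came from a separate mouse, so p-values measure the spread between libraries. Replicates were checked for duplicates: in 110 pairs of libraries of 1 group, the chi-square per degree of freedom over genes with a summed count of at least 20 lay between 12.5 and 155, so no pair agreed within sampling noise.

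The comparisons, gene lists, tests and alternatives were chosen before the data were examined, except where stated. Within each organ, the 4 groups were fitted together with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit and F test, 2-sided, trimmed mean of M values scaling). Genes were kept by edgeR's expression filter with a minimum count of 10 and a minimum total of 15, which left 15892 genes in liver and 17765 in WAT. PTP-r was compared with vehicle within each sex and as the mean of both sexes. The difference between the sexes' effects, the difference between the organs' effects (all 46 libraries, 19135 genes) and the sexes under vehicle were tested too. Benjamini-Hochberg adjusted p-values under 0.05 passed; an edgeR adjusted p in the text means this test with this adjustment. Fold changes are log2 with their standard error (SE), PTP-r relative to vehicle, and levels are CPM, that is counts divided by the scaled library size and brought to a common total, with trimmed mean scaling, given as mean ± SD over libraries.

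A set of 45 gene lists of pathways, resident cell types and tissues that can be carried along in dissection was fixed in advance. Lists with at least 5 tested genes were tested with camera (limma 3.58.1) on voom values with a preset inter-gene correlation of 0.01, which gave 41 lists in liver and 43 in WAT. A camera adjusted p is adjusted over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way, were alternatives. Counts of list members are given over all genes tested and adjusted over the list alone.

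The rule for named genes took the 8 genes with the smallest p in each direction among those that passed with a mean of at least 5 CPM and a gene symbol (the 3 smallest if none passed), 3 members of each list past camera's threshold, up to 4 passing members of each list, and 16 genes fixed in advance. For the sexes under vehicle it took 5 genes in each direction with Xist and Ddx3y. The text prints a subset of the genes this rule gives, and genes outside it are marked where they appear. Some of the genes it gives are not reported here. Alternatives were DESeq2 1.42.0 (Wald test), limma voom with sample quality weights, DESeq2 size factors in the edgeR fit, no expression filter, a filter of 1 CPM in 5 libraries, unstranded counts, low and high title numbers as a term, the numbers in the labels as a block, only the 2 groups compared, and leaving out each library in turn. Leaving out libraries with markers of other tissues was chosen after seeing the data.

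The analysis was tested on simulated counts drawn from the real libraries' means and sizes with 200 genes changed. In liver females (15684 genes) edgeR recovered 62.7% of genes changed 1.5-fold, 83.3% at 2-fold and 93.8% at 4-fold, with 8 false calls among 173. The shares were 56.7%, 77.3% and 96.9% in liver males (9 false of 171) and 79.1%, 93.9% and 98.4% for liver averaged over sexes (11 of 209). In WAT (17663 genes) they were 44.8%, 69.2% and 84.8% in females (9 of 150), 40.3%, 63.1% and 83.3% in males (4 of 136), and 55.2%, 81.5% and 93.9% averaged over sexes (4 of 169). For the difference between organs (18547 genes) they were 52.3%, 64.6% and 80.6% (8 of 146). Comparisons simulated without a change gave 0 calls. DESeq2 made 33 false calls among 187 in the simulated WAT female comparison and 33 among 180 in the male one. Camera called the raised list in each treatment comparison and 0 of 20 unchanged lists. The simulated genes were drawn independently of each other. This run therefore does not test the preset correlation on lists whose genes vary together. The simulated libraries also held no admixed tissue and no outlying library. The shares recovered and the false calls can thus differ in the real libraries, above all in WAT. Figures were drawn with matplotlib 3.10.9; tables were handled with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1. Column 3, which holds the counts of the opposite strand, was used only for the share of the stranded sum, and body weights and histology were not analysed here.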

Results

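Gene expression was measured in liver and white adipose tissue (WAT) of female and male C57BL/6 mice with diet-induced obesity. The mice received a high-fat diet (HFD) for 21 weeks from 7 weeks of age, and from week 16 daily subcutaneous injections of vehicle (phosphate-buffered saline) or PTP-r at 1 mg/kg for 5 weeks. PTP-r is a code name that the labels do not spell out. The series title concerns a mixed-chirality peptide directed at prohibitin and its effects in obesity. Prohibitins are proteins of the inner mitochondrial membrane that are also found at the cell surface. Each organ had 6 female PTP-r, 6 female vehicle, 6 male PTP-r and 5 male vehicle libraries. Counts on genes summed to between 20266425 and 57518893 per liver library and between 20991069 and 32219751 per WAT library. The comparisons ask what PTP-r changed in each organ and sex, and whether the change differed between sexes and between organs.

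The sex labels were checked with Xist, the RNA that silences an X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), and the Y-linked helicase gene Ddx3y (ENSMUSG00000069045, chromosome Y, 1260771 to 1286629). Under vehicle, Xist was at 707.8 ± 127.7 CPM (SD, n = 6) in female liver and 0.0684 ± 0.0630 CPM (n = 5) in male liver, and both genes matched the labels in all 46 libraries. Markers of other tissues were high in a few libraries. Summed skeletal muscle markers reached 461.9 CPM in liver female PTP-r library 11 and 695.8 CPM in vehicle library 12, against a liver median of 17.7 CPM. In WAT they reached 1766 and 553.6 CPM in female PTP-r libraries 1 and 5 and 476.2 CPM in male vehicle library 3, against a median of 105.1 CPM. Pancreas markers summed to 510.3 CPM in liver female PTP-r library 1 (median 23.8 CPM). Epididymis markers summed to 51.0, 134.5 and 81.1 CPM in WAT male PTP-r libraries 1 and 2 and male vehicle library 9 (median 0.867 CPM). B and plasma cell markers summed to 3911 CPM in WAT male PTP-r library 7 (median 943.2 CPM).

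In the liver of females, PTP-r raised inflammatory genes and lowered genes of the endothelium that lines the sinusoids. Saa3, an acute-phase serum amyloid (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), was at 15.5 ± 7.75 CPM (SD, n = 6) with PTP-r and 3.53 ± 1.06 CPM (n = 6) with vehicle (log2 fold change 2.14, SE 0.268, edgeR adjusted p = 0.000746). The neutrophil chemokine Cxcl2 rose by 2.33 and the macrophage elastase Mmp12 by 2.41 on the log2 scale. The DNase gene Dnase1l3 (ENSMUSG00000025279, chromosome 14, 7964533 to 7994573), a sinusoidal endothelial marker, was at 24 ± 4.08 CPM with PTP-r and 43 ± 6.82 CPM with vehicle (log2 fold change -0.85, SE 0.117, edgeR adjusted p = 0.00128). Kdr, the main receptor for vascular endothelial growth factor (ENSMUSG00000062960, chromosome 5, 75932827 to 75978458), fell by 0.75 on the log2 scale, and the junction gene Jam2 fell by 0.83, the netrin gene Ntn4 by 0.75 and the water channel gene Aqp1 by 0.64.

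By fixed list, 4 of 20 cytokine and NF-kB target genes rose in female liver (11 adjusted over the list alone), among them Saa3, Cxcl2, the monocyte chemokine Ccl2 (log2 1.34) and the adhesion molecule Icam1 (0.49). The list had a camera adjusted p of 6.21e-18, and 0.00249 with an estimated correlation. Of 14 sinusoidal endothelial genes 3 fell (10 adjusted over the list alone), and of 24 general endothelial genes 3 fell (15 adjusted over the list alone), with a camera adjusted p of 8.35e-21 for each list and 0.0268 with an estimated correlation. Examples were Flt4, the lymphatic and sinusoidal growth factor receptor (-0.67), Ptprb, a vascular phosphatase (-0.72), and Mmrn2 (-0.59). Of 15 lipid-associated macrophage genes 2 rose, namely Mmp12 and Gpnmb (log2 2.87), and 6 did so adjusted over the list alone (camera adjusted p = 3.88e-07, and 0.0325 with an estimated correlation). Of the 5 neutrophil genes tested, out of 14 listed, 1 rose, S100a9 (0.89), and 4 adjusted over the list alone (camera adjusted p = 1.29e-07, and 0.00714 with an estimated correlation). The other listed neutrophil genes did not pass the expression filter in liver. Of 24 interferon response genes 1 rose, the restriction factor Bst2 (0.37), and 13 adjusted over the list alone. The camera adjusted p was 1.02e-18, and 0.0566 with an estimated correlation. Of 24 acute-phase genes 1 rose, Orm2 (1.67), and 14 adjusted over the list alone. Camera gave an adjusted p of 6.53e-12, and 0.0657 with an estimated correlation. Genes of the cell cycle list had 0 of 24 past the threshold over all genes and 7 adjusted over the list alone (camera adjusted p = 4.9e-11, and 0.109 with an estimated correlation).

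In total 26 of 15892 genes passed in female liver, 12 higher and 14 lower (edgeR), and 1378 had an unadjusted p under 0.05. All 17 of the genes named from this comparison lay on the fitted side of the vehicle mean in 6 of 6 PTP-r libraries. These genes, and those in later counts of this kind, were picked by their p-values in the same libraries. Such agreement is thus not separate support. Limma voom with quality weights gave 6 higher and 20 lower and DESeq2 size factors 16 and 25, so the balance of directions moved with the method. The count was 134 with DESeq2, 5 with only the 2 groups compared and 12 (2 higher and 10 lower) without the libraries high in muscle or pancreas markers, where Saa3 alone of the named genes that rose kept its call and Flt4 alone of those that fell lost it. It was 17, 15, 10 and 52 without vehicle libraries 2, 3, 10 and 12, and 13, 43 and 12 without PTP-r libraries 5, 8 and 11. Aqp1, Cxcl2, Dnase1l3, Jam2, Kdr, Mmp12, Ntn4 and Saa3 passed in each of the 12 fits that left out 1 library, while leaving out vehicle library 10 ended the calls on Icam1, Ccl2, Orm2, Gpnmb, S100a9, Bst2, Flt4, Ptprb and Mmrn2, which ended in between 2 and 10 of the 12 fits.

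In the liver of males most of the same kinds of gene moved and many more passed. Summed markers of B and plasma cells did not move alike in the sexes. In female liver they were at 46.75 to 95.97 CPM with PTP-r and 32.89 to 307.1 CPM with vehicle, the highest in vehicle library 10. In male liver they were at 29.25 to 172.8 CPM with PTP-r and 19.75 to 30.49 CPM with vehicle. Saa3 was at 32.9 ± 4.63 CPM (SD, n = 6) with PTP-r and 2.71 ± 0.983 CPM (n = 5) with vehicle (log2 fold change 3.59, SE 0.299, edgeR adjusted p = 1.26e-07). Icam1, through which leukocytes attach to endothelium (ENSMUSG00000037405, chromosome 9, 21015985 to 21028817), was at 20.3 ± 1.20 CPM with PTP-r and 8.76 ± 1.21 CPM with vehicle (log2 1.21, SE 0.0995, edgeR adjusted p = 1.26e-07). Oas2, an antiviral synthetase induced by interferon (ENSMUSG00000032690, chromosome 5, 120730333 to 120749853), was at 9.77 ± 1.20 CPM with PTP-r and 3.81 ± 0.575 CPM with vehicle (log2 1.35, SE 0.123, edgeR adjusted p = 4.8e-07). The acute-phase gene Lcn2 rose by 3.22 and the lipid-sensing receptor gene Trem2 (ENSMUSG00000023992, chromosome 17, 48346401 to 48354147) by 2.34 on the log2 scale. Dnase1l3 was at 17.4 ± 2.58 CPM with PTP-r and 30.3 ± 2.13 CPM with vehicle (log2 -0.80, SE 0.122, edgeR adjusted p = 0.000182).

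Inflammatory lists rose in male liver. Of 20 cytokine and NF-kB target genes 17 rose (18 adjusted over the list alone), including Ccl2 (log2 2.41) and Vcam1, another leukocyte adhesion molecule (1.33). The list had a camera adjusted p of 9.84e-27, and 0.000183 with an estimated correlation. Of 24 interferon response genes 21 rose (24 adjusted over the list alone), including Oasl2 (1.42) and Ifi44 (1.58). The camera adjusted p was 6.56e-30, and 0.0184 with an estimated correlation. All 5 neutrophil genes tested, out of 14 listed, rose (5 adjusted over the list alone), including S100a9 (2.06) and the receptor gene Csf3r (1.26). Camera gave an adjusted p of 3.7e-09, and 0.00252 with an estimated correlation. Of 15 lipid-associated macrophage genes 8 rose, adjusted either way, including Gpnmb (4.63), the lectin gene Lgals3 (1.95) and Clec7a (1.96). The list had a camera adjusted p of 5.4e-08, and 0.0252 with an estimated correlation. Of 24 acute-phase genes 11 rose (14 adjusted over the list alone), including Saa1 (3.49), Saa2 (3.71) and Steap4 (0.75). The camera adjusted p was 1.61e-13, and 0.0568 with an estimated correlation. Of 23 macrophage genes 13 rose (17 adjusted over the list alone), including the monocyte receptor gene Ccr2 (1.67) and the lysozyme gene Lyz2 (1.28). Camera gave an adjusted p of 2.72e-13, and 0.132 with an estimated correlation. Of 21 T and NK cell genes 4 rose (12 adjusted over the list alone), including Cd2 (1.83) and Cd3d (1.36), and of 24 cell cycle genes 7 rose (11 adjusted over the list alone), including Mki67 (1.19). These 2 lists had camera adjusted p-values of 2.62e-05 and 3.61e-05, and 0.253 and 0.302 with an estimated correlation.

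Endothelial and metabolic lists fell in male liver. Of 14 sinusoidal endothelial genes 8 fell (12 adjusted over the list alone; camera adjusted p = 1.22e-10), including Kdr (log2 -0.69) and Flt4 (-0.71), and of 24 general endothelial genes 7 fell (11 adjusted over the list alone; camera adjusted p = 1.08e-07), including Flt1 (-0.74) and Pecam1, the common endothelial marker (-0.46). With an estimated correlation their adjusted p-values were 0.132 and 0.242. Of 75 nuclear genes of oxidative phosphorylation 16 fell (40 adjusted over the list alone), by small amounts such as Cycs, cytochrome c (-0.31), and Sdha of complex II (-0.17). The list had a camera adjusted p of 6.22e-20, and 0.242 with an estimated correlation. Of 18 genes on the list named for prohibitins and inner membrane quality control 0 fell over all genes and 4 adjusted over the list alone. The median log2 fold change was -0.11 (camera adjusted p = 2.04e-05, and 0.0418 with an estimated correlation). This list also holds other mitochondrial genes, such as Mfn1, Dnm1l and Tfam, so it is not a test of the prohibitins alone. Of 24 genes of fatty acid oxidation 3 fell, including the carnitine carrier gene Slc25a20 (-0.30) and Acadm (-0.32), and of 22 lipid droplet genes 4 fell, including Cidec (-2.21), Plin4 (-1.24) and G0s2 (-1.19). Adjusted over the list alone these counts were 7 and 5, with camera adjusted p-values of 4.03e-06 and 0.000741, and 0.249 for each list with an estimated correlation. The fructose metabolism gene Khk (-0.32), the mitochondrial carrier gene Slc25a10 (-0.50), the phospholyase gene Etnppl (-1.24), the gluconeogenic gene Fbp1 (-0.29) and the detoxification genes Gsta2 (-1.46) and Cyp3a25 (-0.52) fell too. Selenbp2, from the list of male-biased liver genes, rose (2.17).

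In total 1221 of 15892 genes passed in male liver (edgeR), 831 higher and 390 lower, with a median fold of 1.90 for those higher and 1.20 for those lower. Of the 41 named genes 40 lay on the fitted side of the vehicle mean in 6 of 6 PTP-r libraries, and Selenbp2 did so in 5 of 6. The calls on Cidec, Plin4 and G0s2 ended without PTP-r library 1, 5, 7 or 11 or without vehicle library 3 or 4, those on Plin4 and G0s2 also without vehicle library 9, and singly without PTP-r library 6 (Plin4) or vehicle library 12 (G0s2). The log2 fold change of Cidec was -1.23 without vehicle library 4, and that of Saa2, which kept its call, 3.07 without PTP-r library 2. The text names no other gene from this comparison that lost its call when 1 library was left out, and the count ranged from 884 to 1270.

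**Figure D1:**
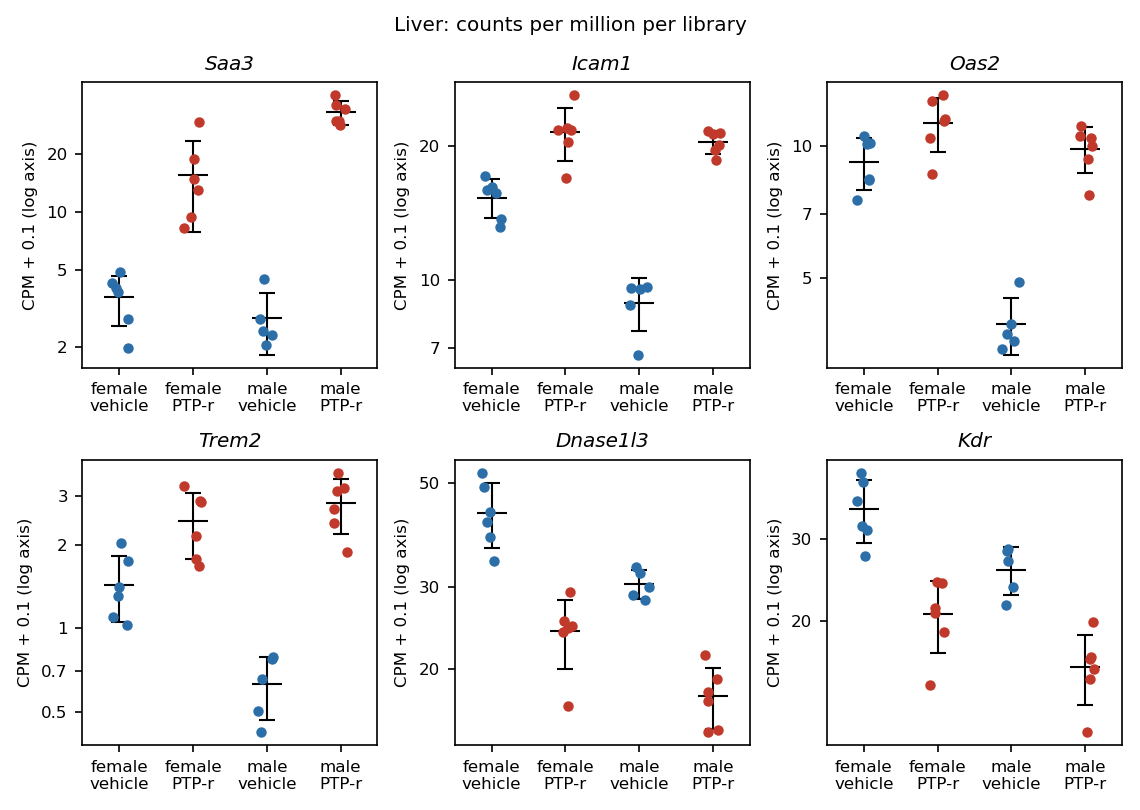
Liver expression of Saa3, Icam1, Oas2, Trem2, Dnase1l3 and Kdr in CPM (plotted as CPM + 0.1 on a log axis) by sex and treatment, with 1 point per library and bars for the mean ± SD of 6 libraries (5 for male vehicle). In males Saa3 averaged 32.9 CPM with PTP-r and 2.71 CPM with vehicle, and Dnase1l3 17.4 and 30.3 CPM.

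Averaged over sexes, inflammatory genes rose and endothelial genes fell in liver. Saa3 rose by 2.86 on the log2 scale (SE 0.20, edgeR adjusted p = 1.05e-08), Icam1 by 0.85, Lgals3 by 1.46, Lcn2 by 2.54 and Orm2 by 1.94. Dnase1l3 fell by 0.82 (SE 0.0846, edgeR adjusted p = 3.02e-06), Ntn4 by 0.80, Jam2 by 0.75, Kdr by 0.72 and Pecam1 by 0.47. Of 24 interferon response genes 22 rose, and of 24 acute-phase genes 14 rose (24 and 18 adjusted over the list alone); their camera adjusted p-values were 7.11e-32 and 7.54e-16, and 0.0135 and 0.0391 with an estimated correlation. Of 14 sinusoidal endothelial genes 10 fell (12 adjusted over the list alone; camera adjusted p = 2.55e-17, and 0.0421 with an estimated correlation). Of 24 general endothelial genes 12 fell (20 adjusted over the list alone; camera adjusted p = 1.61e-15, and 0.0576 with an estimated correlation). Of 28 genes of xenobiotic metabolism 4 fell, adjusted either way (camera adjusted p = 7.44e-05, and 0.0881 with an estimated correlation). Apoa1, the main apolipoprotein of high-density lipoprotein, rose by 0.36. In all 1205 genes passed (edgeR), 824 higher and 381 lower, and of the 20 genes the text names from this comparison 17 had their direction in 12 of 12 PTP-r libraries; the fewest was 7 of 12 for Selenbp2. Female and male libraries share no vehicle library: of the 12 genes higher in females 10 were also higher in males, where 0.627 would be shared by independent lists, and of the 14 lower in females 11 were also lower in males, where 0.344 would be.

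The difference between the sexes' responses in liver was tested directly. Inflammatory genes rose less in females than in males: the female minus male difference was -1.05 for Oas2 (SE 0.164, edgeR adjusted p = 0.00814), -0.72 for Icam1, -0.93 for Oasl2, -1.38 for Clec7a, -0.92 for Irf8, a transcription factor of myeloid cells, and -1.31 for the leukocyte gene Plek (edgeR adjusted p = 0.0435 for each of the last 5). Acot8, a peroxisomal thioesterase gene, differed in the other direction (0.46, edgeR adjusted p = 0.0435). The levels under vehicle also differed between the sexes (edgeR adjusted p = 6.67e-08 for Oas2 and 2.3e-06 for Icam1), with Oas2 at 9.09 ± 1.24 CPM (n = 6) in females and 3.81 ± 0.575 CPM (n = 5) in males, and Icam1 at 15.2 ± 1.54 and 8.76 ± 1.21 CPM. Of 20 cytokine and NF-kB target genes 1 differed over all genes and 8 adjusted over the list alone, all lower in the female response (camera adjusted p = 1.98e-12, and 0.0181 with an estimated correlation). Of 24 interferon response genes 2 differed, and 13 adjusted over the list alone (camera adjusted p = 2.83e-15, and 0.134 with an estimated correlation). Of 23 macrophage genes 0 differed over all genes and 14 adjusted over the list alone (camera adjusted p = 1.9e-14, and 0.148 with an estimated correlation). Of 14 sinusoidal endothelial genes 0 differed either way (camera adjusted p = 0.965).

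In all 17 of 15892 genes differed between the sexes' responses in liver (edgeR), 1 higher and 16 lower, and 1588 had an unadjusted p under 0.05; DESeq2 gave 207, and the fits without an expression filter, on unstranded counts or with low and high title numbers as a term gave 4 each. Oas2 passed in each of the 23 fits that left out 1 library, and the other genes named here lost their call in 15 to 19 of them. The count became 4, 5, 66, 46, 4 and 5 without female vehicle libraries 2, 3, 6, 7, 10 and 12, and 8, 79, 4, 5 and 4 without female PTP-r libraries 4, 5, 8, 9 and 11. It became 110, 8, 4, 5, 4 and 4 without male PTP-r libraries 1, 2, 5, 6, 7 and 11, and 30, 11, 4, 5 and 4 without male vehicle libraries 3, 4, 9, 10 and 12. It was 6 without the libraries high in muscle or pancreas markers.

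In the WAT of females, no gene passed with PTP-r, and the lowest edgeR adjusted p was 0.0515. Ucp1, the uncoupling protein of thermogenic fat (ENSMUSG00000031710, chromosome 8, 83290352 to 83298452), averaged 138.5 ± 211.6 CPM (SD, n = 6) with PTP-r and 0.0843 ± 0.0946 CPM (n = 6) with vehicle (edgeR adjusted p = 0.0515). PTP-r libraries 1 and 4 held 394.1 and 428.5 CPM, PTP-r libraries 5 and 8 held 3.89 and 4.00 CPM, and each of the other WAT libraries of either sex held at most 1.51 CPM. The lipid droplet gene Cidea had a log2 fold change of 4.68 (edgeR adjusted p = 0.0552), with 95.1 and 102 CPM in PTP-r libraries 1 and 4, 1.18 to 4.10 CPM in the other 4 and 0.698 to 2.66 CPM with vehicle. Without libraries 1 and 4 it was 0.94 (edgeR adjusted p = 0.297). Apln, a peptide of vascular growth (log2 -1.15), the chemokine receptor gene Cxcr4 (-1.18) and Gramd3 (-0.59) had an edgeR adjusted p of 0.0515 each, and Saa3 was at 5.59 ± 1.42 CPM with PTP-r and 26.1 ± 19 CPM with vehicle (edgeR adjusted p = 0.0552). Lep, the satiety hormone leptin (ENSMUSG00000059201, chromosome 6, 29060220 to 29073877), was at 933.9 ± 443.7 CPM with PTP-r and 2118 ± 843.9 CPM with vehicle (log2 -1.18, edgeR adjusted p = 0.0808).

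By fixed list in female WAT, 14 of 20 thermogenic adipocyte genes and 13 of 16 skeletal muscle genes were higher adjusted over the list alone, and 0 over all genes. The camera adjusted p was 3.45e-06 for each list, and 0.819 with an estimated correlation. Skeletal muscle markers summed to 1766 and 269.4 CPM in PTP-r libraries 1 and 4, the libraries with the most Ucp1, and to 553.6 and 254.6 CPM in libraries 5 and 8, against at most 199.1 CPM with vehicle. Of 23 genes of fatty acid oxidation 10 were higher and of 26 extracellular matrix genes 6 were lower adjusted over the list alone, with camera adjusted p-values of 2.76e-05 and 0.000336, and 0.819 for each with an estimated correlation. Of 75 nuclear oxidative phosphorylation genes 2 were higher adjusted over the list alone (camera adjusted p = 3.74e-15, and 0.819 with an estimated correlation). The count past the threshold was 0 of 17765 (edgeR) with 2909 at an unadjusted p under 0.05; DESeq2 called 616 and limma voom with quality weights 371, a filter of 1 CPM in 5 libraries gave 20, and fitting only the 2 groups gave 3. It was 32 without the libraries high in muscle markers and 123 without the male libraries high in epididymis markers, which enter the shared estimate of the spread. It was 7 and 1 without vehicle libraries 3 and 12, and 21, 194, 1 and 67 without PTP-r libraries 5, 8, 9 and 11. Apln and Saa3 passed without vehicle library 3 or PTP-r library 5, 8 or 11, Ucp1 without PTP-r library 5, 8, 9 or 11, Cidea, Cxcr4 and Gramd3 without PTP-r library 5, 8 or 11, and Lep without PTP-r library 8.

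In the WAT of males, genes of cholesterol synthesis fell with PTP-r. Lss, the synthase that closes the sterol rings (ENSMUSG00000033105, chromosome 10, 76531588 to 76557138), was at 39.4 ± 6.54 CPM (SD, n = 6) with PTP-r and 83.6 ± 12.9 CPM (n = 5) with vehicle (log2 fold change -1.08, SE 0.178, edgeR adjusted p = 0.0122). Cyp51 fell by 0.97, Hsd17b7 by 0.95, Mvd of the mevalonate pathway by 0.99 and Ebp by 0.38 on the log2 scale. Matrix genes fell, with Sparc (ENSMUSG00000018593, chromosome 11, 55394500 to 55423183) at -0.70 and the basement membrane collagens Col4a1 at -0.61 and Col4a2 at -0.70. Gpx3, a secreted glutathione peroxidase (ENSMUSG00000018339, chromosome 11, 54902453 to 54910377), rose by 1.04 (SE 0.198, edgeR adjusted p = 0.0216), and Irf7 (0.81), Apoe (0.67), Cbx7 (0.77), Vnn1 (1.17), Cyp27a1 (0.49) and Pck1 (1.21), the enzyme of glyceroneogenesis in fat, rose too. The acute-phase gene Serpina3n fell by 0.63, S100a8 by 1.74 and the vascular cadherin gene Pcdh12 by 0.75.

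By fixed list in male WAT, 10 of 24 cholesterol synthesis and uptake genes fell (20 adjusted over the list alone; camera adjusted p = 8.98e-22, and 0.0787 with an estimated correlation). Of 26 extracellular matrix genes 3 fell (10 adjusted over the list alone; camera adjusted p = 1.64e-08, and 0.864 with an estimated correlation). Of 24 interferon response genes 1 rose, Irf7 (12 adjusted over the list alone; camera adjusted p = 4.26e-07, and 0.864 with an estimated correlation). All 12 mesothelial genes, markers of the lining of the body cavity, were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 1.47e-07, and 0.864 with an estimated correlation). In all 155 of 17765 genes passed (edgeR), 82 higher and 73 lower, with 3698 at an unadjusted p under 0.05, and the 18 genes named here had their direction in 6 of 6 PTP-r libraries. PTP-r library 1 stood apart on the second principal component of WAT (142.9, with the next highest library at 56.1) and had the most detected genes of the WAT libraries, 28935. DESeq2 called 1173, limma voom with quality weights 1120 and the fit without an expression filter 35. The count was 4, 12, 41 and 51 without the libraries high in markers of muscle, of epididymis, of lymphoid cells and in Ucp1. It was 14, 0, 39 and 47 without vehicle libraries 3, 4, 9 and 12 and 84, 272, 33 and 41 without PTP-r libraries 1, 2, 6 and 7, so each gene named here lost its call without vehicle library 4; Lss, Cyp51, Hsd17b7, Irf7 and Pcdh12 lost it in no other fit that left out 1 library. Of these 5, Irf7 alone kept its call without the libraries high in muscle markers, and Cyp51 and Hsd17b7 without those high in epididymis markers.

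**Figure D2:**
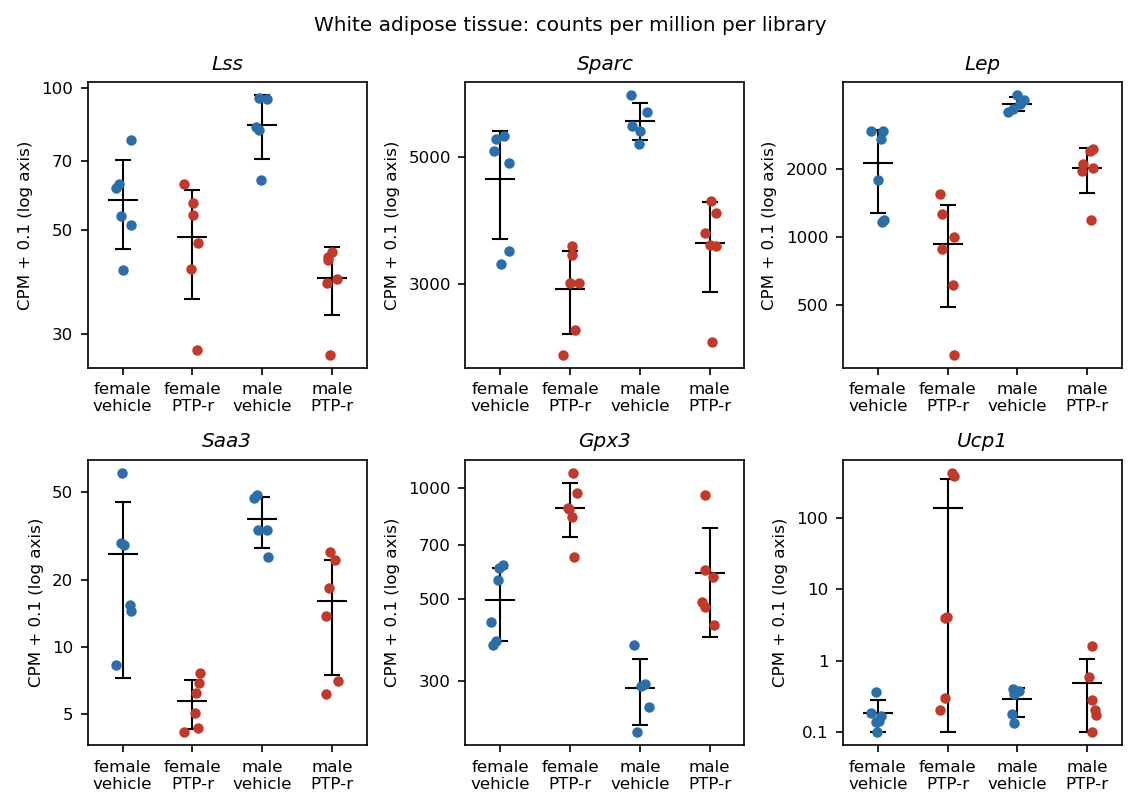
WAT expression of Lss, Sparc, Lep, Saa3, Gpx3 and Ucp1 in CPM (plotted as CPM + 0.1 on a log axis) by sex and treatment, with 1 point per library and bars for the mean ± SD of 6 libraries (5 for male vehicle). Lss averaged 39.4 CPM with PTP-r and 83.6 CPM with vehicle in males, and Ucp1 reached 394.1 and 428.5 CPM in 2 of the female PTP-r libraries.

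Averaged over sexes, WAT showed lower cholesterol synthesis and matrix genes and a lower level of leptin. None of these genes passed in WAT of females alone (edgeR). Lss fell by 0.67 (SE 0.123, edgeR adjusted p = 0.00677), Hsd17b7 by 0.66 and Idi1 by 0.53 on the log2 scale, and 18 of 24 cholesterol synthesis and uptake genes fell (20 adjusted over the list alone). Their camera adjusted p was 2.98e-16, and 0.235 with an estimated correlation. Sparc fell by 0.67 (SE 0.106, edgeR adjusted p = 0.00393), Col4a2 by 0.59, Col6a1 by 0.52 and Col6a2 by 0.65; of 26 extracellular matrix genes 8 fell (9 adjusted over the list alone; camera adjusted p = 1.28e-07, and 0.804 with an estimated correlation). Lep fell by 1.06 (SE 0.216, edgeR adjusted p = 0.010), from 3866 ± 263.1 CPM (n = 5) to 2018 ± 452.5 CPM (n = 6) in males. Angptl8, an inhibitor of lipoprotein lipase, fell by 1.47, the desaturase gene Scd2 by 0.92 and the fatty acid binding protein gene Fabp5 by 0.64. Saa3 fell by 1.72 (edgeR adjusted p = 0.00472), S100a8 by 1.39, Serpina3n by 0.65, Lbp, which binds bacterial lipopolysaccharide, by 0.78, Apln by 0.81 and Pcdh12 by 0.69 (edgeR adjusted p = 0.00159).

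Genes that rose in WAT averaged over sexes included Gpx3 (log2 0.94, edgeR adjusted p = 0.00338), Irf7 (0.65), Vnn1 (1.10) and Pck1 (0.87). Of 19 circadian clock genes 5 rose, including Hlf (0.70), Nr1d1 (0.55) and Nr1d2 (0.43), and 1 fell (8 and 2 adjusted over the list alone; camera adjusted p = 0.0312, and 0.804 with an estimated correlation). Of 20 thermogenic adipocyte genes 3 rose, namely Fabp3 (4.01), Cidea (2.55) and Cox8b (1.30), and 9 adjusted over the list alone (camera adjusted p = 0.0389, and 0.804 with an estimated correlation); the 2 female PTP-r libraries with the most Ucp1 also held 1766 and 269.4 CPM of skeletal muscle markers. Without them these 3 calls ended, with log2 fold changes of 2.05, 0.68 and 0.66, as they did without the libraries high in epididymis markers (2.89, 2.50 and 1.34); that of Fabp3 was 3.18 without male PTP-r library 1. Of 24 interferon response genes 4 rose (9 adjusted over the list alone; camera adjusted p = 3.55e-05, and 0.804 with an estimated correlation). In all 1258 of 17765 genes passed (edgeR), 649 higher and 609 lower. Of the 38 genes the text names from this comparison 24 had their direction in 12 of 12 PTP-r libraries, and the fewest was 10 of 12, as for Fabp3. DESeq2 called 2297, limma voom with quality weights 2099 and the fit without an expression filter 385; leaving out the libraries high in markers of muscle, in those of epididymis or in Ucp1 gave 430, 760 and 427. The count was 643 and 780 without female PTP-r libraries 4 and 9, 582, 754 and 626 without female vehicle libraries 6, 10 and 12, and 631, 466, 712 and 729 without male vehicle libraries 3, 4, 9 and 12. Without female vehicle library 6 or male vehicle library 3 or 4, the calls on Nr1d1, Nr1d2 and Cox8b ended. Those on Nr1d1 and Cox8b also ended without female PTP-r library 4, that on Cox8b without female vehicle library 12 and that on Nr1d1 without male vehicle library 9.

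The responses of the sexes in WAT were compared directly, and 0 of 17765 genes differed (edgeR); 1520 had an unadjusted p under 0.05, limma voom with quality weights called 0 and DESeq2 86. The smallest p-values were those of Cyp27a1, a sterol hydroxylase gene (female minus male log2 difference -0.71, SE 0.125, edgeR adjusted p = 0.113), and the kinase gene Stk38l (0.72, SE 0.132, edgeR adjusted p = 0.113). Cyp27a1 passed without female vehicle library 3 or female PTP-r library 11, and Stk38l without the latter; the count was 1 without female vehicle library 3, female PTP-r library 9 or male PTP-r library 1 and 13 without female PTP-r library 11. Of 24 cholesterol synthesis and uptake genes 0 differed over all genes and 5 adjusted over the list alone, with a median difference of 0.41 (camera adjusted p = 1.84e-10, and 0.596 with an estimated correlation).

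The response of liver was set against that of WAT in a single fit of all 46 libraries. Inflammatory genes moved apart: the liver minus WAT difference was 4.57 for Saa3 (SE 0.374, edgeR adjusted p = 5.94e-11), 2.71 for Ccl2, 2.87 for Orm2, 2.87 for S100a8, 2.00 for Lgals3, 4.31 for Gpnmb, 1.72 for Cxcr4, 1.33 for Tlr2, a receptor for bacterial lipoproteins, 1.08 for Lbp and 0.84 for Serpina3n. The difference for Gpnmb was 3.57 without WAT female vehicle library 6. Of 26 extracellular matrix genes 4 were higher in the liver response (11 adjusted over the list alone; camera adjusted p = 2.9e-08, and 0.290 with an estimated correlation), including Sparc (0.88) and Col4a2 (0.87). Of 24 general endothelial genes 6 were lower, including Flt1 (-0.66), with 1 higher and 9 lower adjusted over the list alone (camera adjusted p = 4.53e-06, and 0.462 with an estimated correlation). Jam2 (-0.88), Cd300lg (-0.87), Vnn1 (-1.17) and the clock gene Hlf (-0.87) were lower too. Of 22 cytokine and NF-kB target genes 16 differed (19 adjusted over the list alone), all higher in the liver response (camera adjusted p = 1.62e-25, and 0.00188 with an estimated correlation). Of 7 neutrophil genes tested, out of 14 listed, 4 were higher in the liver response (5 adjusted over the list alone). Camera gave an adjusted p of 1.09e-05, and 0.00188 with an estimated correlation. Of 75 oxidative phosphorylation genes 14 were lower in the liver response (49 adjusted over the list alone). Their camera adjusted p was 2.64e-22, and 0.290 with an estimated correlation. In all 1032 of 19135 genes differed between organs (edgeR), 572 higher and 460 lower, and limma voom with quality weights called 1718. Of genes tested in both organs, 29 rose in both (30.1 if independent) and 25 fell in both (13.5 if independent, Fisher's exact p = 0.00285), while 24 rose in liver and fell in WAT (29.5 if independent) and 5 fell in liver and rose in WAT (13.7 if independent, Fisher's exact p = 0.0113).

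**Figure D3:**
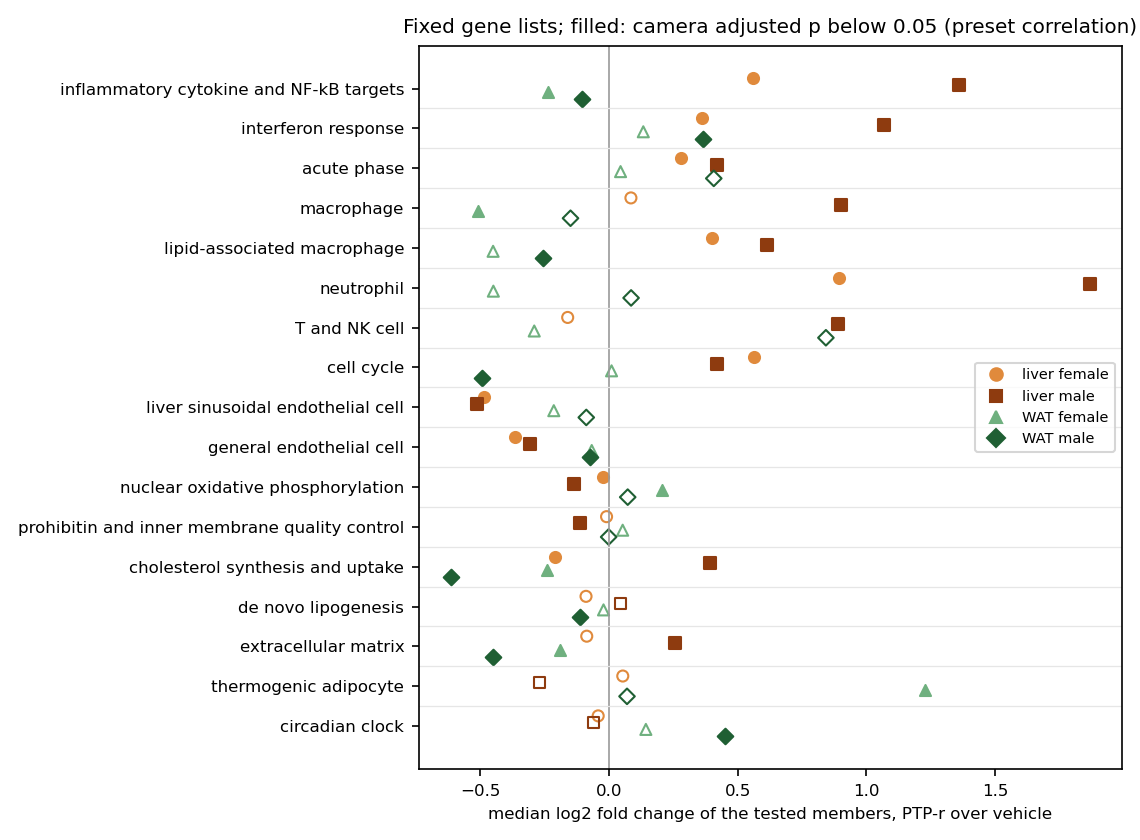
Median log2 fold change of PTP-r against vehicle over the tested members of 17 fixed gene lists in liver and WAT of each sex; each point is a list and filled points passed camera's adjusted p of 0.05. The cytokine and NF-kB list had a median of 1.36 in male liver and -0.24 in female WAT.

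The prohibitin genes, named in the series title, did not pass in any edgeR treatment comparison. Phb (ENSMUSG00000038845, chromosome 11, 95666957 to 95680773) was at 57.6 ± 2.29 CPM with PTP-r and 57.0 ± 4.30 CPM with vehicle in female liver, and at 62.4 ± 4.02 and 67.9 ± 2.68 CPM in male liver (log2 -0.12, edgeR adjusted p = 0.185). Phb2 (ENSMUSG00000004264, chromosome 6, 124712336 to 124716950) was at 162.6 ± 4.13 and 164.2 ± 8.69 CPM in female liver and at 159.9 ± 6.30 and 172.0 ± 4.98 CPM in male liver (log2 -0.11, edgeR adjusted p = 0.139). In WAT, Phb was at 97.6 ± 11.9 and 99.7 ± 9.02 CPM in females and 80.2 ± 8.02 and 84.3 ± 4.84 CPM in males, and Phb2 at 135.2 ± 10.6 and 119.4 ± 16.8 CPM in females and 102.1 ± 7.02 and 102.0 ± 3.49 CPM in males (SD, n = 6, or 5 for male vehicle). The 4 within-sex edgeR adjusted p-values of Phb ranged from 0.185 to 0.972 and those of Phb2 from 0.139 to 0.978. Anxa2, the annexin that binds prohibitin at the surface of adipose endothelium (ENSMUSG00000032231, chromosome 9, 69453620 to 69491795), fell by 0.45 in WAT averaged over sexes (SE 0.125, edgeR adjusted p = 0.0343, 12 of 12 libraries). Its call ended without female PTP-r library 4, female vehicle library 6, 10 or 12, or male vehicle library 3, 4, 9 or 12. Among the other genes fixed in advance, Adipoq, Fgf21, Gdf15, Cyp7a1, Fasn, Scd1 and Col1a1 did not pass in any treatment comparison in which they were tested.

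The sexes differed under vehicle in both organs. In liver, 23 of 24 female-biased genes were higher in females, adjusted either way (camera adjusted p = 5.3e-15, and 0.0212 with an estimated correlation), such as Cyp2c40 (log2 8.0), and 19 of 20 male-biased genes were lower, adjusted either way (camera adjusted p = 5.3e-15, and 0.125 with an estimated correlation). Arsa, arylsulfatase A, was lower in females by 2.63 on the log2 scale (SE 0.112, edgeR adjusted p = 4.6e-14). Of 21 T and NK cell genes 19 and of 23 macrophage genes 18 were higher in female liver, and of 19 lipogenesis genes 13 were lower (19, 19 and 13 adjusted over the list alone). These lists had camera adjusted p-values of 1e-05, 5.39e-09 and 2.68e-05, and 0.276 for each with an estimated correlation. In WAT, 14 of 16 lipid-associated macrophage genes and 23 of 24 cell cycle genes were lower in females, and 54 of 75 oxidative phosphorylation genes were higher (14, 24 and 64 adjusted over the list alone). Their camera adjusted p-values were 2.43e-09, 5.4e-16 and 6.07e-16, and 0.691 for each with an estimated correlation. Kdm6a, an X-linked demethylase gene, was higher in female WAT by 0.82 (SE 0.0606, edgeR adjusted p = 1.19e-08), and Nrn1 by 5.62. In all 5835 genes differed in liver (edgeR), 3064 higher and 2771 lower in females, and 4787 in WAT, 2420 higher and 2367 lower.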

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

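The tests on Zic1, attached skeletal muscle, dilution by leukocytes and single endothelial genes were chosen after the patterns they address were seen. So were those on GC content and gene length and on time of day or feeding. The fits without libraries high in markers of other tissues were also chosen after the results they bear on were seen.

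In female WAT, Ucp1 was at 394.1 and 428.5 CPM in PTP-r libraries 1 and 4 and at most 4.00 CPM in the other 21 WAT libraries. Classical brown fat in the sampled piece was to show as Zic1 above the other libraries; Zic1 was at 0 CPM in both libraries and at most 0.0393 CPM in the others. A gene this near the floor in all 23 libraries excludes nothing. Attached skeletal muscle could bring neighbouring brown fat along, and the lower of the summed muscle markers in these libraries, 269 CPM, lay above the highest female vehicle value of 199 CPM. Female PTP-r libraries 5 and 8, with 553.6 and 254.6 CPM of muscle markers, held 3.89 and 4.00 CPM of Ucp1, and the other 8 female libraries at most 199.1 and 0.268 CPM, while male vehicle library 3 held 476.2 CPM of muscle markers with 0.0773 CPM of Ucp1; a response of these mice to PTP-r and tissue attached in dissection cannot be told apart with so few libraries.

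In liver, the sinusoidal endothelial list fell with a median log2 fold change of -0.525 averaged over sexes (bootstrap interval -0.648 to -0.322). Dilution of resident cells by incoming leukocytes would lower hepatocyte and stellate cell genes alike. The hepatocyte median was -0.0567 (interval -0.117 to -0.00801) and the stellate median -0.129 (interval -0.292 to 0.00609), both above the sinusoidal interval. For these genes this argues against dilution as the whole cause. The intervals resample the genes of a list, so they do not measure the spread between libraries. Fewer endothelial cells with the same expression per cell would move all endothelial genes together, but 18 of 37 members moved against the mean of the others, such as Dnase1l3 (-0.467) and Kdr (-0.361) below it and Cd93 (0.531) and Plvap (0.427) above it. This argues against a uniform loss of all endothelial cells as the only change. The members pool sinusoidal and general endothelial genes, and some may also be expressed in other cells. A loss of only some endothelial cells was not tested and stays open. A change of state of these cells with PTP-r also remains open as a hypothesis that was not tested.

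In WAT, the cholesterol synthesis list fell with a median log2 fold change of -0.47 averaged over sexes. This fall did not rest on the libraries with the most muscle markers, lymphoid markers or Ucp1. The weakest median without each of these sets of libraries was -0.458, with 11 to 17 of 24 genes past the threshold. The Ucp1-high libraries were female and the lymphoid-marker library was male. Leaving them out therefore left the libraries of the other sex in place. Smaller amounts of these tissues in the remaining libraries were not tested. Without the libraries high in epididymis markers the median was -0.473. The remaining male libraries still held 1.796 to 11.32 CPM of these markers with vehicle and 0.3102 to 1.215 CPM with PTP-r. That fit therefore cannot decide on epididymis in males. These fits did not address mesothelial markers, at 296.4 to 689.7 CPM with PTP-r and 176 to 271.3 CPM with vehicle in males, or those of exocrine pancreas, at 20.2 to 46.7 and 53.3 to 58.3 CPM, so these tissues stay open in males; in females the ranges overlapped (301 to 765.2 and 257.7 to 787.9 CPM, and 5.85 to 20.7 and 10.9 to 38.9 CPM). GC content and gene length were tested with 1000 matched gene sets, of which 0 had a median as low (the lowest was -0.131), which argues against them. Another time of day or feeding state stays open, since the clock genes that passed in WAT had a median of -0.0412 in liver in the WAT direction, but only 2 of them differed between organs; so does a response to PTP-r in fat, which was not tested apart from food intake or body weight.

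A test for a single library far from the rest of its group was run on 70 groups of printed levels and library totals and found 9. Chance would flag about 1 in 20 groups (3.5) if the values were normally distributed. Levels near the floor, as in several of these groups, are not, so the 9 cannot be read as more than chance. In liver, male PTP-r library 11 had the highest Xist of its group (0.104 CPM) and the highest Ddx3y (78.4 CPM). In WAT, Ucp1 was highest in female vehicle library 6 (0.268 CPM) and male PTP-r library 2 (1.51 CPM), and Xist in male vehicle library 10 (1.06 CPM); Lss was lowest in male PTP-r library 1 (27.1 CPM). Ddx3y was highest in female PTP-r library 8 (0.0727 CPM) and female vehicle library 10 (0.0332 CPM), and lowest in male vehicle library 12 (53.3 CPM).

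The test of the difference between the sexes' responses in liver passed for Acot8 (0.46), Oas2 (-1.05), Icam1 (-0.72), Oasl2 (-0.93), Irf8 (-0.92), Clec7a (-1.38) and Plek (-1.31), as female minus male log2 differences. The test of the difference between organs passed, as liver minus WAT, for Saa3 (4.57), Orm2 (2.87), Ccl2 (2.71), Cxcr4 (1.72), Tlr2 (1.33), Serpina3n (0.84), Lbp (1.08), S100a8 (2.87), Lgals3 (2.00) and Gpnmb (4.31). It also passed for Sparc (0.88), Col4a2 (0.87), Jam2 (-0.88), Cd300lg (-0.87), Flt1 (-0.66), Hlf (-0.87) and Vnn1 (-1.17). Shares of reads that name no gene and library totals were compared between PTP-r and vehicle in 20 exact permutation tests, of which 0 passed (lowest adjusted p = 0.303).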

How the results depend on the processing

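The fits without libraries high in markers of other tissues were chosen after the results were seen; where a count moved, the cause was not tested unless named. With DESeq2 size factors all 175 results on named genes kept their direction and side of the threshold, and the liver female count became 41. The DESeq2 Wald test, which made 33 false calls in each simulated WAT comparison within a sex, gave 134 in liver females, 207 for the liver sex difference, 616, 1173 and 2297 in WAT females, males and averaged over sexes, and 86 for the WAT sex difference. Limma voom with quality weights gave 371, 1120 and 2099 in WAT females, males and averaged, and 1718 between organs. Under these weights the general endothelial list in WAT males reversed (adjusted p = 0.446). Without an expression filter, so with more genes to adjust over, the liver sex difference had 4, WAT males 35 and WAT averaged 385; with the filter of 1 CPM in 5 libraries WAT females had 20. Unstranded counts and low and high title numbers as a term each gave 4 for the liver sex difference, and fitting only the 2 groups gave 5 in liver females and 3 in WAT females. Without the libraries high in muscle or pancreas markers, the liver female count was 12 and the liver sex difference 6. In WAT females, males and averaged the counts were 32, 4 and 430 without the muscle-marker libraries and 123, 12 and 760 without the epididymis-marker libraries. WAT males had 41 without the lymphoid-marker library and 51 without the Ucp1-high libraries, which lowered the averaged count to 427. Whether the numbers in the labels pair the samples was not settled. All 23 title numbers carried the same sex and treatment in both organs, as they would if both organs came from 1 mouse. Deviations in libraries of both organs with the same title number had correlations of -0.0293 to 0.176 (23 pairs, 4 best with their own number). Low correlation between different organs cannot exclude a shared mouse. The pairs of the description number had -0.232 to 0.0802 in liver (0 of 5 best with their own) and -0.135 to 0.238 in WAT (1 of 5). With the description number as a block the counts were 0 in liver females, 0 in liver males, 26 averaged and 0 for the sex difference. They were 4, 0 and 0 in WAT females, males and averaged. Only 5 of these numbers held both treatments in an organ, 1 of them in males and the rest in females. In males the block nearly coincides with treatment, so the counts that involve males say nothing on stability. In females it does so less, and the calls in liver females did not hold under this block, which leaves fewer libraries to compare. The block could not be estimated for the sexes under vehicle. The title number as a block between organs gave 903 and changed no call on the 17 named genes. With an estimated correlation camera called 6, 5, 6 and 1 lists in liver females, males, averaged and for the sex difference (18, 21, 17 and 16 with the preset one). It called 1 list for the sexes under vehicle in liver, 2 between organs, and 0 in each of WAT females, males, averaged, the sex difference and the sexes under vehicle. Fry called 9 in liver females, 7 for the liver sex difference, 7 between organs and 0, 1, 1 and 0 in WAT females, males, averaged and for the sex difference. Leaving out 1 library at a time gave between 10 and 52 genes in liver females, 884 and 1270 in males, 997 and 1301 averaged, 4 and 110 for the sex difference and 5186 and 5926 for the sexes under vehicle. In WAT it gave between 0 and 194 in females, 0 and 272 in males, 466 and 1652 averaged, 0 and 13 for the sex difference and 3574 and 4772 for the sexes under vehicle, and between organs 779 and 1429. Of 3348 such results on named genes 2935 kept their side of the threshold, 388 lost a call, 25 gained one and 0 reversed. In simulated counts edgeR recovered 44.8% of genes changed 1.5-fold in WAT females and 62.7% in liver females, so changes of that size can be missed.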

Other observations

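In liver averaged over sexes, genes of cell division rose: of 24 cell cycle genes 10 rose (14 adjusted over the list alone), such as Cdk1, the kinase that starts mitosis (log2 0.85), Tpx2 (1.08) and Bub1b (0.66). Camera gave an adjusted p of 1.31e-09, and 0.123 with an estimated correlation. Of 20 male-biased liver genes 3 rose, Serpina1e (1.87), Selenbp2 (1.10) and C8b (0.54), and 4 adjusted over the list alone (camera adjusted p = 0.0652). The glutathione transferase genes Gsta2 (-1.29) and Gstt3 (-0.46) fell. Opa1, which shapes the inner mitochondrial membrane, fell by 0.11 on the log2 scale, in 11 of 12 libraries (edgeR adjusted p = 0.0473). The calls on C8b, Selenbp2 and Opa1 ended in 7, 13 and 17 of the 23 fits that left out 1 library, each without female PTP-r library 5, female vehicle library 6, male PTP-r library 5 or male vehicle library 4 or 12. Of 19 circadian clock genes, 19 lipogenesis genes and 18 chaperone genes of the endoplasmic reticulum, 0 passed in liver over all genes or adjusted over the list alone (edgeR).

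In WAT averaged over sexes, hypoxia and vascular signalling genes moved both ways: of 24 genes 1 rose, Hif3a (0.73), and 4 fell, including Apln, Hif1a (-0.31) and Vldlr (-0.45), with 4 and 8 adjusted over the list alone (camera adjusted p = 0.297). Of 25 adipocyte genes 2 rose, Cfd, the complement factor adipsin (1.08), and Pck1 (0.87), and 1 fell, Lep (-1.06), with 4 and 2 adjusted over the list alone (camera adjusted p = 0.559). Of 23 genes of fatty acid oxidation 3 rose, including Acot2 (0.45) and Vnn1 (1.10), with 4 adjusted over the list alone (camera adjusted p = 0.11). Chaperone genes of the endoplasmic reticulum had 3 of 18 lower, Dnajb11 (-0.20), Sel1l (-0.21) and Edem1 (-0.26), with 3 higher and 4 lower adjusted over the list alone (camera adjusted p = 0.11). The progenitor genes Sema3c (-0.64) and Fap (-0.50) fell. The calls on Hif1a, Hif3a, Cfd, Sel1l, Edem1 and Fap ended in 7 to 16 of the 23 fits that left out 1 library, each of them without female PTP-r library 4 or 9, female vehicle library 12 or male vehicle library 3 or 4. That on Dnajb11 ended only without male vehicle library 4.

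Other splits of the same libraries, 100 per comparison with the real one included, were refitted with edgeR. Where only 1 split, the real one, gave as many genes, chance assignment to the groups was unlikely, at 1 in 100 splits. This held in liver for females (26 genes, highest other split 6), males (1221 and 17), averaged over sexes (1205 and 1), the sex difference (17 and 8) and the sexes under vehicle (5835 and 1732), for WAT averaged over sexes (1258 and 124) and its sexes under vehicle (4787 and 1), and between organs (1032 and 185). The splits for the sex difference and between organs shuffled treatment, which removes the treatment effect itself. They cannot tell whether effects that are equal in both sexes or organs would give such counts. Chance assignment could not be excluded in WAT males. There 5 of 100 splits, the real one included, gave at least 155 genes and the highest other gave 381. In WAT females and the WAT sex difference the real count was 0 (edgeR), which all 100 splits reach whatever the libraries hold, so the splits decide nothing there; the highest others gave 208 and 57. In these comparisons 2909 and 1520 genes had an unadjusted p under 0.05, and DESeq2 called 616 and 86. A split of male WAT libraries with 381 genes, and one of female WAT libraries with 208, point to a structure of the samples whose source was not tested.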
